A study of Rattus norvegicus with 30 samples.

How the data were processed

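The data were 30 Affymetrix rat expression arrays of biotin-labelled RNA from primary rat hepatocytes: vehicle, 1 µM and 100 µM BNF at 24 and 48 h, with 5 arrays per group. Per the labels, frozen cells were purchased, cultured and dosed once, and each replicate was a separate well. The study was 1 of several compound studies run at different times, each with its own vehicle, and only this compound is used here. Replicate numbers follow the order of the samples and only name an array.

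The deposited values are linear signal intensity per probe set, made with MAS5 per the submitters' processing notes, with no version given. The values of all 30 arrays have a trimmed mean (2% trimmed at each end) near 1500, so each array had been scaled to a common level before deposit. Background correction, scanner settings and filters are not given in the sources used here. Such scaling fixes the mean of each array, so a change shared by most genes cannot be seen. The table had 31099 probe sets, of which 57 control probe sets were left out of the tests. The platform annotation gave 20826 probe sets 1 gene symbol, 436 several and 9780 none. Gene numbers of 20764 of the first matched the reference gene table (assembly GRCr8), which was used for names alone. A gene was represented by its probe set with the highest mean log2 signal, giving 14217 genes, 4525 of which had over 1 probe set. Probe sets with several symbols or none were left out of the gene tests. Of the 167 genes named in the text, 1 (Cyp2c13) rested on a probe set whose suffix marks shared sequence with other genes. No column of another sample was present (0), and no genome was used here.

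Deposited intensities were taken to log2 with no constant and no further normalization. Analyses used R 4.3.3 and limma 3.58.1. One model with a mean per group was fitted to all 30 arrays (24 residual degrees of freedom) with eBayes and a mean-variance trend. Contrasts, 9 in all, were each dose against vehicle at each time, 100 against 1 µM at each time, vehicle at 48 against 24 h, and the difference of the effects between times at each dose. P-values were adjusted by Benjamini-Hochberg over all genes and called at 0.05, and a 2-fold count required an absolute log2 fold change of at least 1. SE is the standard error of the log2 fold change, and folds are 2 to the power of that value. All 26 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within each contrast, and again with a correlation estimated from the data. Counts of list members are given over all genes tested and with p-values adjusted over the list alone.

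The lists were AhR battery, NRF2 targets, CAR and PXR targets, sex-dependent P450s, phase II conjugation, fatty acid oxidation and PPARA targets, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, glucose metabolism, hepatocyte secreted proteins, liver-enriched transcription factors, urea cycle and amino acid catabolism, acute phase, interferon response, p53 targets, ER stress and amino acid response, heat shock, cell cycle, cytoskeleton and dedifferentiation, oxidative phosphorylation, and markers of Kupffer cells, stellate cells, endothelial cells, cholangiocytes and lymphocytes. The lists, the contrasts and the rule for named genes were fixed before the data were examined. For the contrasts with vehicle the rule took all AhR battery members and the 10 highest and 10 lowest log2 fold changes among genes called, with groups that did not overlap and a higher group mean above the median of all genes. It also took up to 4 members with the smallest adjusted p from each other list called, in the direction of the list. For other contrasts it took 5 genes in each direction and the list members, without the condition on overlap for the effects between times. Genes outside this rule are said to be so where they are named.

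Arrays were compared on median signal, interquartile range, the 3' minus 5' difference of the Gapdh and beta-actin controls and the level of the spiked controls, by two-sided exact permutation tests in 35 comparisons. The smallest p was 0.02381 before adjustment and 0.4445 after (exact permutation, with 0.00794 the smallest possible). A single comparison at the smallest possible p could not pass after adjustment over the 35. The p of 0.02381 was for the median signal at 48 h, 398.57 at 1 µM against 376.94 in vehicle. At 24 h these were 397 and 375.33 (exact permutation p = 0.05556, adjusted p = 0.4445). Centring each array on its median, an alternative below, removes such a difference. No pair of arrays was identical (0). The closest pair had a mean absolute log2 difference of 0.377, against a median of 0.412 within groups, so all arrays were kept as separate replicates.

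The model was tested on simulated data in the setting of 1 µM against vehicle at 24 h, with 14217 genes and 200 changed genes per round over 10 rounds. It recovered 49.7% of changes of 0.5 log2 units, 72.1% of 1 and 85.8% of 2, and 5.34% of its calls were false. All 10 of 10 raised lists were found and 0 unshifted lists were called. The simulated genes were drawn independently of each other, so false list calls from correlated genes were not tested. In the real data the estimated correlation reached 0.43, for hepatocyte secreted proteins. Alternatives were quantile normalization, centring each array on its median, log2 of the signal plus 16, genes above the median of mean signal alone, no mean-variance trend, array weights, a fit of the compared groups alone, all non-control probe sets (31042), other probe sets of a named gene, a block for rounds of serial numbers, and leaving out each array in turn.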

Results

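Gene expression was measured in primary hepatocytes of male Sprague Dawley rats exposed to beta-naphthoflavone (BNF), a synthetic flavone and ligand of the aryl hydrocarbon receptor (AhR), the transcription factor that switches on Cyp1a1 and related genes. Frozen hepatocytes were thawed, plated and treated with 1 µM BNF, 100 µM BNF or the vehicle, 1% dimethyl sulfoxide (DMSO), and RNA was taken 24 and 48 h later. Each of the 6 groups held 5 arrays, 30 in all, from separate culture wells per the labels. The labels do not tie the wells to animals, so the p-values measure the spread between wells. The number of arrays limits the precision. The median gene had an SD of 0.19 to 0.21 log2 units within a group. Signals were compared for 14217 genes, and gene calls below are at an adjusted p of 0.05 in limma. The design asks what each dose changed at each time, whether the doses differed, and whether the effects differed between the times.

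The AhR battery, a set of 8 measured AhR target genes, rose at both doses and both times. Cyp1a1, the AhR-induced cytochrome P450, had a signal of 11832 ± 3140 (SD, n = 5) in vehicle at 24 h, 44100 ± 3275 at 1 µM and 59383 ± 8936 at 100 µM. At 48 h the Cyp1a1 signals were 9524.7 ± 4287 in vehicle, 22607 ± 5173 at 1 µM and 50727 ± 6829 at 100 µM. These were rises of 3.83-fold and 5.13-fold at 24 h and of 2.49-fold and 5.68-fold at 48 h. Cyp1a2, a related P450, rose 1.55-fold and 2.19-fold at 24 h and 2.17-fold and 3.45-fold at 48 h. Nqo1, a quinone reductase, rose 1.63-fold and 1.84-fold at 24 h and 1.38-fold and 1.71-fold at 48 h. Cyp1b1 and Tiparp, an ADP-ribosyltransferase that represses AhR, changed at 100 µM: Cyp1b1 rose 7.50-fold at 24 h and 3.82-fold at 48 h, and Tiparp 3.09-fold and 2.42-fold. At 1 µM the Cyp1b1 log2 fold changes were 0.31 (adjusted p = 0.341) at 24 h and 0.16 (adjusted p = 0.78) at 48 h, and those of Tiparp 0.25 (adjusted p = 0.0581) and 0.02 (adjusted p = 0.949). Aldh3a1, an aldehyde dehydrogenase, rose 5.21-fold at 100 µM and 24 h, and its log2 fold change at 48 h was 0.99 (adjusted p = 0.0643). The size of its changes is limited by a low vehicle signal, 114 ± 68.5 (SD, n = 5) at 24 h and 125 ± 69.02 (SD, n = 5) at 48 h. The Aldh3a1 rise at 1 µM and 24 h, 2.54-fold (adjusted p = 0.0323), was lost in a fit of those 2 groups alone (adjusted p = 0.12) and without any 1 of vehicle replicates 1, 2 and 3 or BNF replicates 1, 2, 3 and 4, with adjusted p between 0.0544 and 0.0978. Cyp2s1 and Ahrr, the AhR repressor gene, passed the test in no comparison. Ahrr had a low signal of 87.19 ± 122.7 (SD, n = 5) in vehicle at 24 h, at percentile 7.73 of the gene means. The SE of its log2 fold changes against vehicle was 0.7373, so the test cannot tell whether Ahrr responded. The Cyp1a1 call at 1 µM and 48 h was lost in a fit of those 2 groups alone (adjusted p = 0.0529), while Aldh3a1 was called at 100 µM and 48 h without vehicle 48 h replicate 2 (adjusted p = 0.0155) or with quantile normalization (adjusted p = 0.0479). Tiparp was called at 1 µM and 24 h without vehicle 24 h replicate 5 (adjusted p = 0.0378), with quantile normalization (adjusted p = 0.038), without genes below the median mean signal (adjusted p = 0.0324) and in another probe set (adjusted p = 0.0149). The Cyp1a1 value comes from 1 probe set that was among the brightest on the treated arrays: at 100 µM and 24 h a mean of 90.2 of 31099 probe sets were brighter, against 1369 in vehicle.

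**Figure D1:**
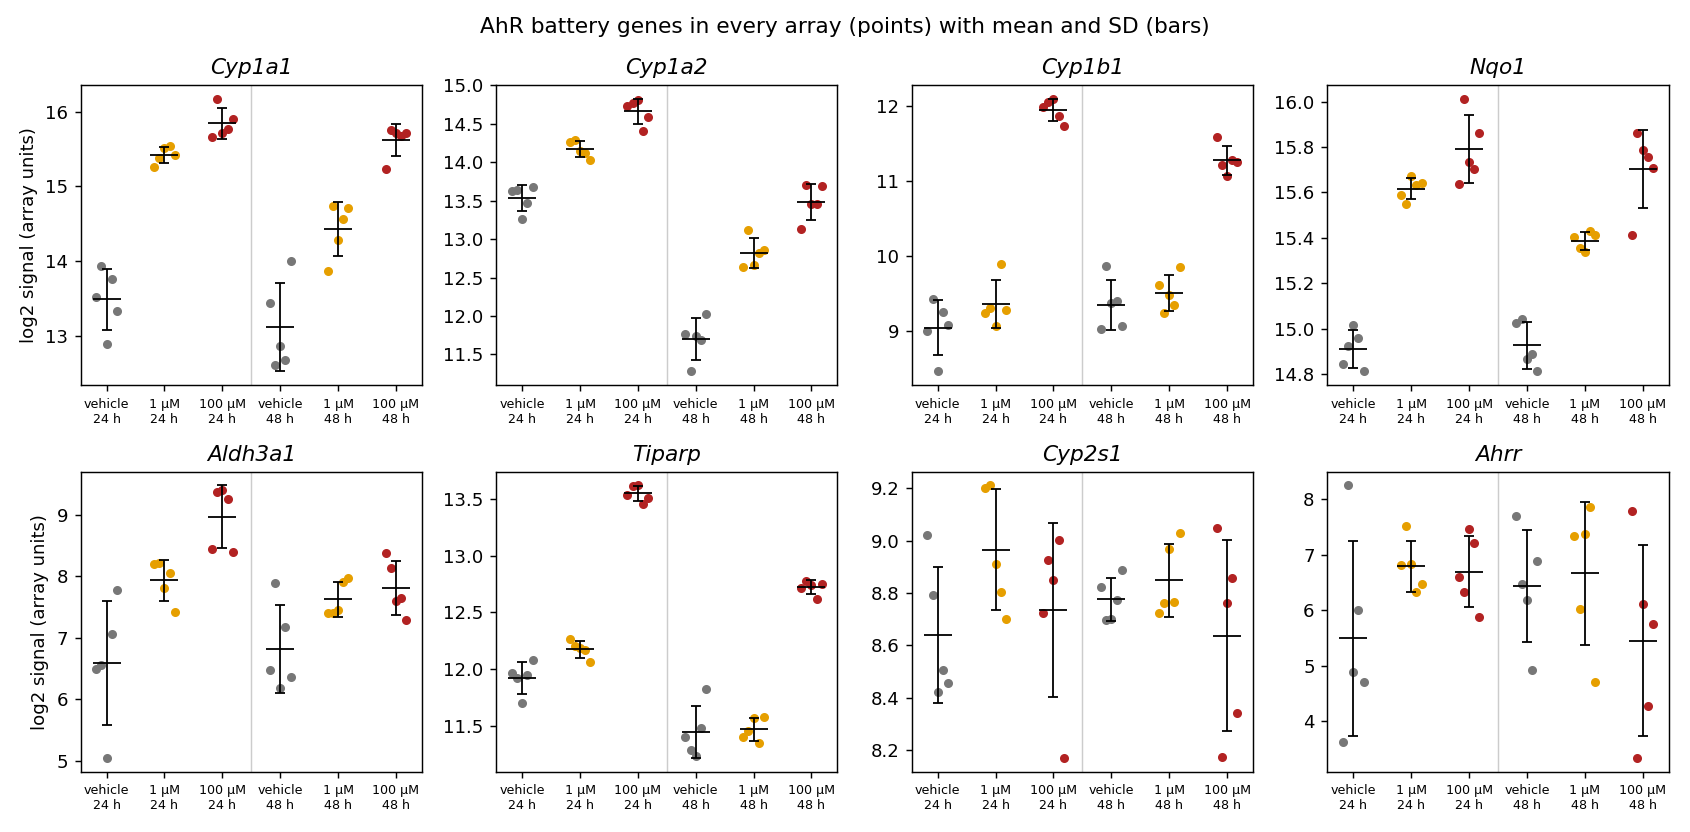
Log2 signal (array units) of the 8 measured AhR battery genes in every array, with points for arrays of vehicle (grey), 1 µM (orange) and 100 µM (red) and black bars for the mean and SD of 5 arrays at 24 and 48 h; each panel has its own axis range. Cyp1a1 signals averaged 11832 in vehicle and 44100 at 1 µM at 24 h, while Cyp1b1 averaged 541.09 and 670.5 in those groups and 3975.9 at 100 µM.

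At 1 µM for 24 h, AhR targets rose and genes of fuel and lipid metabolism fell. The AhR battery rose in 4 of 8 members (5 adjusted over the list alone; camera adjusted p = 4.08e-09). Beyond the battery, Hsd17b2, a steroid dehydrogenase, rose 2.03-fold (log2 fold change 1.02, SE 0.14), Cyp2a1, a testosterone hydroxylase, 1.96-fold, and the chemokine Cxcl1 1.74-fold. Gamt, which makes creatine, fell 2.07-fold, and Gucy2c, a guanylate cyclase receptor, 1.81-fold. Fatty acid synthesis genes fell in 7 of 17 (7 lower and 1 higher adjusted over the list alone), among them Acly 1.80-fold, Fasn 1.66-fold, Pklr 1.57-fold and Acaca 1.41-fold. Fatty acid oxidation genes fell in 10 of 24 (14 lower and 1 higher adjusted over the list alone), with Fabp1, a fatty acid binding protein, down 1.47-fold and Acaa2, a thiolase, down 1.26-fold. Other probe sets of Acaca, Fasn (adjusted p = 0.316) and Acaa2 (adjusted p = 0.24) were lower without passing the test. Glucose metabolism genes fell in 6 of 12 (8 adjusted over the list alone), including Gys2, liver glycogen synthase, 1.76-fold and Fbp1, a gluconeogenic enzyme, 1.61-fold. Bile acid synthesis and transport genes fell in 4 of 18 (4 adjusted over the list alone), with the bile acid uptake carrier Slc10a1 down 1.79-fold. These 4 falling lists kept their call with an estimated correlation.

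In total 612 genes changed at 1 µM and 24 h, 271 higher and 341 lower, of which 29 changed at least 2-fold. The groups did not overlap for 739 genes, 5.2% of genes against 0.794% by chance. The other 7 lists called lower lost their call with an estimated correlation. They were the urea cycle and amino acid catabolism list (6 of 21 lower, 7 lower and 1 higher adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), hepatocyte secreted proteins (5 of 20 lower, 6 adjusted over the list alone; adjusted p = 0.24) and cholesterol synthesis (4 of 20 lower, 4 adjusted over the list alone; adjusted p = 0.0884). The remaining 4 were phase II conjugation (3 of 21 lower, 6 lower and 1 higher adjusted over the list alone; adjusted p = 0.413), targets of the xenobiotic receptors CAR and PXR (2 of 11 lower, 4 adjusted over the list alone; adjusted p = 0.101), liver-enriched transcription factors (2 of 16 lower, 2 adjusted over the list alone; adjusted p = 0.105) and oxidative phosphorylation (1 of 19 lower, 5 adjusted over the list alone; adjusted p = 0.24). NRF2 targets, with 1 of 19 higher (3 adjusted over the list alone), were not called (adjusted p = 0.063) but were called without BNF 1 µM 24 h replicate 1 (adjusted p = 0.0158), replicate 2 (adjusted p = 0.0092) or vehicle 24 h replicate 5 (adjusted p = 0.0373), and with quantile normalization (adjusted p = 0.00168). The NRF2 member called higher over all genes was Nqo1, which is also in the AhR battery. The call of the transcription factors was also lost without genes below the median mean signal (adjusted p = 0.0579). The 5 lists of markers of other liver cell types were not called, with 1 of their 60 measured markers, Lox, lower (2.03-fold; adjusted p = 0.536 in another probe set). Stellate cell markers had a median of 0.05, a mean of -0.10 and a test pointing down, and endothelial markers a median of 0.37 (adjusted p = 0.294). Centring each array on its median gave 395 genes, 51 higher and 344 lower, and leaving out BNF 1 µM 24 h replicate 3 gave 406.

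At 100 µM for 24 h 3000 genes changed, antioxidant and AhR genes rose and metabolic gene lists fell. Among the highest were Cyp1b1 (7.50-fold), Aspg (5.63-fold; log2 fold change 2.49, SE 0.50), Hsd17b2 (4.30-fold), Cyp2a1 (3.93-fold) and Gdf15, a stress-induced cytokine (2.63-fold). Among the lowest were Dpys, a pyrimidine-degrading enzyme (log2 fold change -2.85, SE 0.56), Uroc1, of histidine breakdown (4.85-fold lower), and Ccn2, a matricellular protein (4.85-fold lower). Low signals limit the size of 2 of these changes: Aspg had a signal of 249 ± 124 (SD, n = 5) in vehicle, and Dpys 168 ± 122.5 (SD, n = 5) at 100 µM. NRF2 targets, genes of the antioxidant response, rose in 13 of 19 members (15 adjusted over the list alone; adjusted p = 0.00246 with an estimated correlation). The cystine carrier Slc7a11 rose 2.01-fold and Gclm, of glutathione synthesis, 1.47-fold. The AhR battery rose in 6 of 8 (6 adjusted over the list alone). Glucose metabolism genes fell in 10 of 12 (10 adjusted over the list alone), including Pfkfb1 3.88-fold and Slc37a4, the glucose-6-phosphate carrier, 2.55-fold. Urea cycle and amino acid catabolism genes fell in 16 of 21 (17 adjusted over the list alone), with Cdo1 down 2.20-fold and Fah 1.79-fold. Fatty acid oxidation genes fell in 20 of 24 (20 adjusted over the list alone), with Cyp4a1 down 2.68-fold and Angptl4 2.61-fold.

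Lipid and bile acid genes fell at the same dose and time. Fatty acid synthesis fell in 8 of 17 and rose in 2 (9 and 2 adjusted over the list alone), with Pklr down 2.52-fold and the lipogenic regulator Srebf1 2.35-fold. Cholesterol synthesis fell in 13 of 20 (16 adjusted over the list alone), with Dhcr7 down 1.63-fold and Sqle 1.48-fold. Bile acid synthesis and transport fell in 9 of 18 and rose in 1 (10 and 2 adjusted over the list alone), with Cyp8b1, the sterol 12-alpha-hydroxylase, down 4.10-fold and Slc10a1 2.83-fold. Liver-enriched transcription factors fell in 8 of 16 (8 adjusted over the list alone), among them Nr1h4, the bile acid receptor, 1.52-fold and Nr1i2, the receptor PXR, 1.36-fold. These lists kept their calls with an estimated correlation. Lists that did not were hepatocyte secreted proteins (9 of 20 lower, 10 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), acute phase (9 of 17 lower, 9 adjusted over the list alone; adjusted p = 0.0982) and interferon response (6 of 18 lower and 1 higher, with the same counts adjusted over the list alone; adjusted p = 0.236). The others were ER stress and amino acid response (9 of 21 higher and 2 lower, 11 and 2 adjusted over the list alone; adjusted p = 0.19) and oxidative phosphorylation (6 of 19 lower, 10 lower and 1 higher adjusted over the list alone; adjusted p = 0.236). Among ER stress genes Sdf2l1 rose 1.59-fold and Chac1, which degrades glutathione, 1.29-fold.

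Of the 3000 genes at 100 µM and 24 h, 1523 were higher and 1477 lower, and 283 changed at least 2-fold, 101 higher and 182 lower. The groups did not overlap for 2106 genes, 14.8% against 0.794% by chance. Of the other cell types' markers, Kupffer cell markers were higher in 1 of 15 and stellate cell markers lower in 3 of 17, with the same counts adjusted over the list alone, and none of these lists was called (adjusted p = 0.927 and 0.225). Phase II conjugation genes, with 8 of 21 lower and 3 higher (the same adjusted over the list alone), were not called (adjusted p = 0.0685) but were without vehicle 24 h replicate 1 (adjusted p = 0.036) or BNF 100 µM 24 h replicate 2 (adjusted p = 0.0233) and with median centring (adjusted p = 0.0489). CAR and PXR targets (adjusted p = 0.995) had a median of -0.07 and a mean of 0.07, sex-dependent P450s (adjusted p = 0.518) -0.01 and 0.16, and p53 targets (adjusted p = 0.42) 0.09 and -0.03. With each array centred on its median, 30.4% of the genes called were higher, against 50.8% here. The interferon call was lost without vehicle 24 h replicate 1 (adjusted p = 0.0512), vehicle 24 h replicate 4 (adjusted p = 0.0625) or BNF 100 µM 24 h replicate 1 (adjusted p = 0.0662), and without genes below the median mean signal (adjusted p = 0.316).

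At 1 µM for 48 h, 115 genes changed. Cyp2a1 rose 2.39-fold (log2 fold change 1.26, SE 0.06), Cyp1a2 2.17-fold, Akr1b8, an aldo-keto reductase, 1.56-fold and Nqo1 1.38-fold. Crp, C-reactive protein, fell 2.08-fold (log2 fold change -1.06, SE 0.12), Gamt 1.70-fold, Ccn2 1.67-fold, Ugt2b 1.66-fold, Rdh7, a retinol dehydrogenase, 1.63-fold and Scd, the stearoyl-CoA desaturase, 1.58-fold. The AhR battery rose in 3 of 8 (3 adjusted over the list alone) and the fatty acid oxidation list fell, with 2 of 24 members called lower (9 adjusted over the list alone), Pdk4 by 1.46-fold and Angptl4 by 1.40-fold. Other probe sets of Pdk4 (adjusted p = 0.709) and Ugt2b (adjusted p = 0.0538) were lower without passing the test. These 2 lists kept their call with an estimated correlation (adjusted p = 0.00781 and 0.014).

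The other 10 lists called lower at 1 µM and 48 h lost their call with an estimated correlation. Glucose metabolism had 3 of 12 lower (4 adjusted over the list alone; adjusted p = 0.089 with an estimated correlation), with Pfkfb1 down 1.59-fold (adjusted p = 0.0543 in a fit of those 2 groups alone). CAR and PXR targets had 3 of 11 lower (4 adjusted over the list alone; adjusted p = 0.0827) and fatty acid synthesis 2 of 17 lower (5 adjusted over the list alone; adjusted p = 0.0827). Secreted proteins (9 adjusted over the list alone; adjusted p = 0.106), phase II conjugation (4; adjusted p = 0.322), cholesterol synthesis (2; adjusted p = 0.137) and acute phase (3; adjusted p = 0.326) had 1 member lower each over all genes. Bile acid synthesis and transport (adjusted p = 0.0827), urea cycle and amino acid catabolism (adjusted p = 0.299) and oxidative phosphorylation (adjusted p = 0.192) had 0 of their 18, 21 and 19 members called over all genes or adjusted over the list alone. The acute phase call was also lost without BNF 1 µM 48 h replicate 3 (adjusted p = 0.067) or vehicle 48 h replicate 5 (adjusted p = 0.166) and with quantile normalization, where the median was 0.05 against -0.08 here (adjusted p = 0.695). The bile acid call was lost without vehicle 48 h replicate 5 (adjusted p = 0.0695) and the phase II call with quantile normalization (adjusted p = 0.092). ER stress genes, with 0 of 21 called over all genes or adjusted over the list alone, were not called (adjusted p = 0.0641) but were called lower with median centring (adjusted p = 0.00731). They were also called lower without BNF 1 µM 48 h replicate 1 (adjusted p = 0.0342) or 4 (adjusted p = 0.0409) or vehicle 48 h replicate 3 (adjusted p = 0.03) or 5 (adjusted p = 0.0223). NRF2 targets (adjusted p = 0.54) were called higher with quantile normalization (adjusted p = 0.0102), the transcription factors lower without vehicle 48 h replicate 2 (adjusted p = 0.0431), and the cytoskeleton genes without vehicle 48 h replicate 3 (adjusted p = 0.03) and without genes below the median mean signal (adjusted p = 0.0229). Nqo1, shared with the AhR battery, was the only NRF2 target called higher over all genes. Of the other cell types' markers 0 of 60 changed over all genes, and Kupffer cell (1 higher and 2 lower), stellate cell (1 lower) and cholangiocyte markers (1 lower) had members adjusted over the list alone. The stellate cell list, with a median of 0.28 here (adjusted p = 0.497), was called lower without genes below the median mean signal, where it held 2 markers (median -0.54, adjusted p = 0.0119). Cholangiocyte markers had a median of 0.20 and a mean of 0.13 with a test pointing down (adjusted p = 0.688). Of the 115 genes 41 were higher and 74 lower, with 13 changed at least 2-fold. The groups did not overlap for 372 genes, 2.62% against 0.794% by chance. Median centring gave 66 genes, 8 higher and 58 lower, and a fit of these 2 groups alone gave 30. The count lay between 46 and 76 without any 1 of vehicle 48 h replicates 1, 3, 4 and 5 or BNF 1 µM 48 h replicates 1, 3, 4 and 5.

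At 100 µM for 48 h the antioxidant and AhR genes were higher and hepatocyte metabolic genes lower. Cd24, a surface glycoprotein, rose 7.94-fold (log2 fold change 2.99, SE 0.40), Cyp1a1 5.68-fold, Cyp2a1 3.85-fold, Mest 3.70-fold and Akr1b8 3.29-fold. The Cd24 fold rests on a low vehicle signal of 119 ± 34.5 (SD, n = 5), at percentile 16.4 of the gene means, against 915 ± 122 (SD, n = 5) at 100 µM. Gckr, the glucokinase regulator, fell 9.01-fold (log2 fold change -3.17, SE 0.32), Ftcd, of histidine breakdown, 7.09-fold, Ccn2 6.42-fold, the intermediate filament gene Vim 5.53-fold, Crp 5.34-fold and the fatty acid carrier Cd36 4.77-fold. Gckr had a low signal of 249 ± 171 (SD, n = 5) at 100 µM, which limits the size of its fall. NRF2 targets rose in 15 of 19 (15 adjusted over the list alone; adjusted p = 0.000574 with an estimated correlation), with Slc7a11 up 2.28-fold, Gclc, of glutathione synthesis, 1.97-fold and Pgd, of the pentose phosphate pathway, 1.60-fold. The AhR battery rose in 5 of 8 (6 adjusted over the list alone). Glucose metabolism fell in 9 of 12 (9 adjusted over the list alone), with Pfkfb1 down 5.26-fold and Slc37a4 3.11-fold. Urea cycle and amino acid catabolism fell in 17 of 21 (18 lower and 1 higher adjusted over the list alone), including Bhmt, betaine-homocysteine methyltransferase, 4.04-fold and Cps1, the first urea cycle enzyme, 2.11-fold. Fatty acid oxidation fell in 17 of 24 (18 lower and 1 higher adjusted over the list alone), with Cyp4a1 down 3.68-fold and Fabp1 2.97-fold.

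Acute phase genes fell at 100 µM and 48 h in 12 of 17 (14 adjusted over the list alone), among them Steap4 3.44-fold and Cp, ceruloplasmin, 1.82-fold. Secreted proteins fell in 12 of 20 (16 adjusted over the list alone), including Itih4 1.93-fold and the coagulation factor F9 1.76-fold. Fatty acid synthesis fell in 10 of 17 and rose in 2 (10 and 4 adjusted over the list alone), with Thrsp down 3.04-fold and Scd 2.55-fold. Bile acid synthesis and transport fell in 7 of 18 and rose in 1 (8 and 1 adjusted over the list alone), with Cyp8b1 down 3.80-fold and the bile salt export pump Abcb11 2.11-fold. Cholesterol synthesis fell in 9 of 20 (11 adjusted over the list alone), with Sqle down 1.31-fold, and liver-enriched transcription factors in 7 of 16, with 1 higher (7 and 1 adjusted over the list alone), among them Nr1i3, the receptor CAR, 2.28-fold. These lists kept their call with an estimated correlation. Phase II conjugation (8 of 21 lower and 4 higher, the same adjusted over the list alone; adjusted p = 0.439 with an estimated correlation) and oxidative phosphorylation (6 of 19 lower, 9 adjusted over the list alone; adjusted p = 0.188) did not. The sulfotransferases Sult1a1 and Sult1b1 fell 3.44-fold and 2.45-fold.

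Lists not called at 100 µM and 48 h included CAR and PXR targets (2 higher and 4 lower of 11, the same adjusted over the list alone; adjusted p = 0.2), sex-dependent P450s (1 higher and 2 lower of 7, the same adjusted over the list alone; adjusted p = 0.93) and interferon response (1 higher and 5 lower of 18, 2 and 5 adjusted over the list alone; adjusted p = 0.152). The p53 targets had 4 higher and 4 lower of 15 (the same adjusted over the list alone; adjusted p = 0.806), and ER stress genes 8 higher and 2 lower of 21 (8 and 3 adjusted over the list alone; adjusted p = 0.104). Heat shock genes (1 higher and 3 lower of 10, 2 and 3 adjusted over the list alone; adjusted p = 0.905), cell cycle genes (1 higher and 1 lower of 27, 0 adjusted over the list alone; adjusted p = 0.818) and cytoskeleton genes (3 higher and 8 lower of 22, 3 and 9 adjusted over the list alone; adjusted p = 0.101) were not called either. Markers of other cell types had the following members lower and none higher: Kupffer cell 2 of 15 (2 adjusted over the list alone; adjusted p = 0.101), stellate cell 2 of 17 (1; adjusted p = 0.905), endothelial 1 of 11 (1; adjusted p = 0.927), cholangiocyte 1 of 7 (1; adjusted p = 0.414) and lymphocyte 0 of 10 (0; adjusted p = 0.93). Cholangiocyte markers had a median of -0.18, a mean of 0.11 and a test pointing down, and lymphocyte markers a median of 0.15 and a test pointing down.

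In total 2475 genes changed at 100 µM and 48 h, 1250 higher and 1225 lower, and 252 changed at least 2-fold, 50 higher and 202 lower. The groups did not overlap for 1897 genes, 13.3% against 0.794% by chance. The phase II call was lost without BNF 100 µM 48 h replicate 1 (adjusted p = 0.062), and that of the transcription factors when genes below the median mean signal were left out (adjusted p = 0.0737). Kupffer cell markers were called lower without vehicle 48 h replicate 1 (adjusted p = 0.0494), and cytoskeleton genes without vehicle 48 h replicate 3 (adjusted p = 0.0454) or BNF 100 µM 48 h replicate 5 (adjusted p = 0.0359), and both lists without genes below the median mean signal (adjusted p = 0.0494 and 0.0318).

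**Figure D2:**
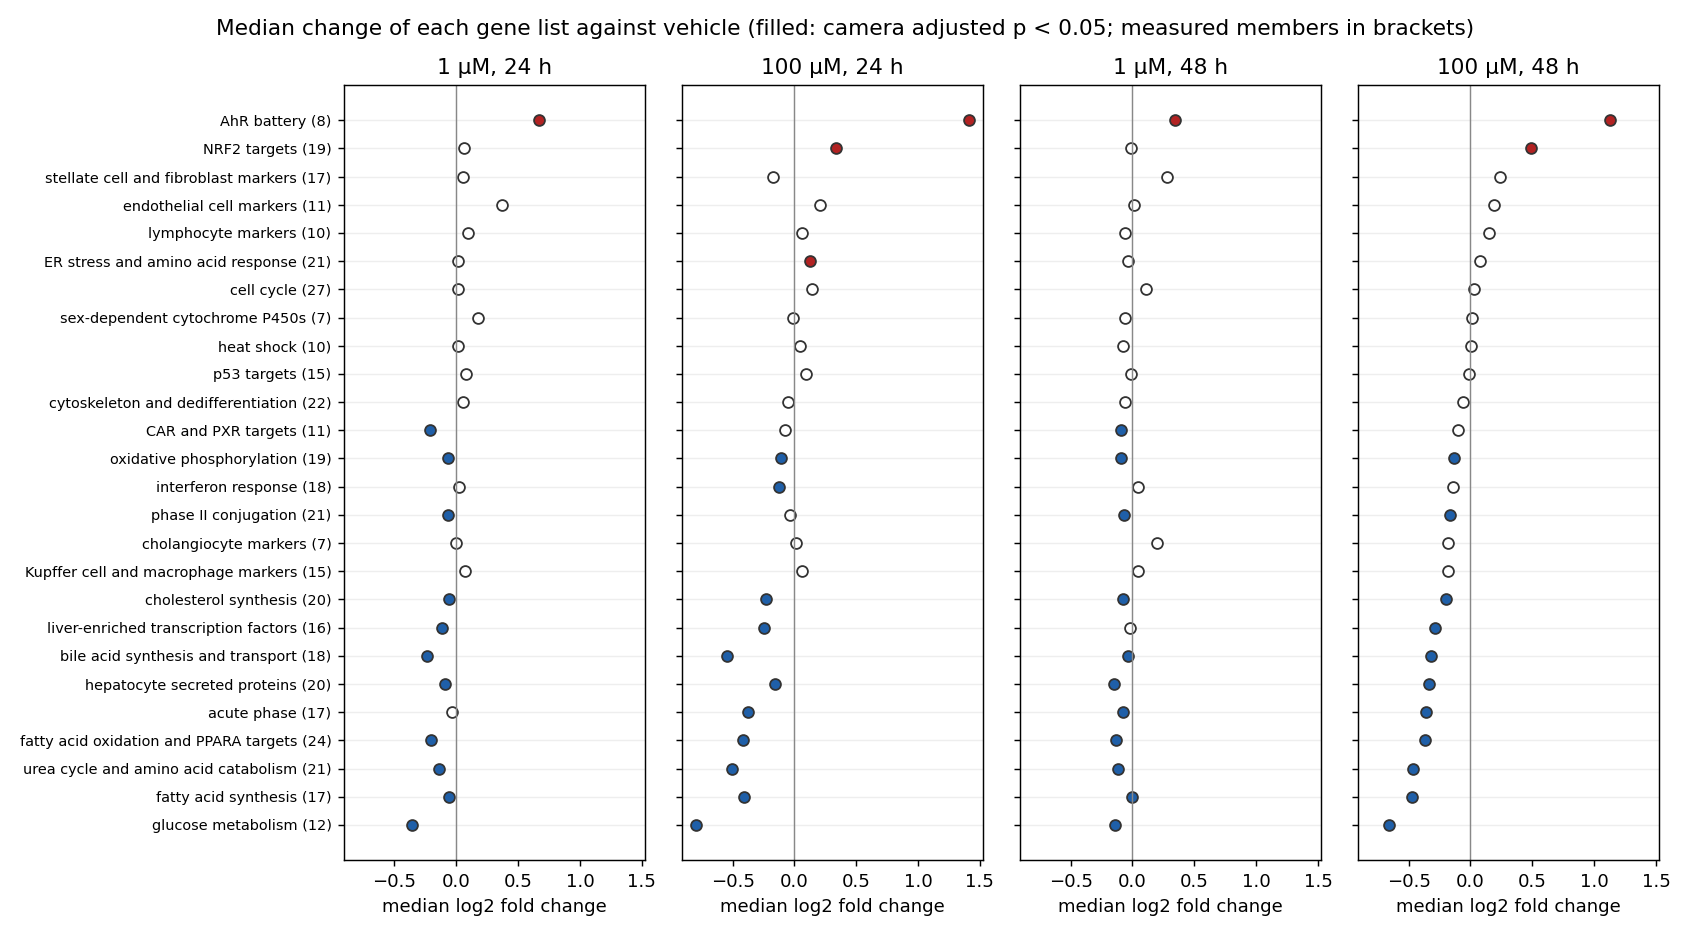
Median log2 fold change against vehicle of the members of each of the 26 gene lists (measured members in brackets) in the 4 comparisons of BNF with vehicle, with filled points for lists called by camera, red where the test pointed up and blue where it pointed down, and open points for lists not called. The AhR battery had medians of 0.67, 1.41, 0.34 and 1.13 from left to right, and glucose metabolism -0.36, -0.80, -0.14 and -0.66.

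The doses were compared directly. At 24 h 1097 genes differed between 100 and 1 µM, 447 higher and 650 lower at 100 µM, and 72 of them at least 2-fold. Cyp1b1 was 6.03-fold, Ugt2b1, a glucuronosyltransferase, 3.45-fold and Tiparp 2.59-fold higher at 100 µM, while Cyp8b1 was 3.23-fold and Ccn2 2.91-fold lower. The Cyp1a1 differences between doses were singled out after their values were seen. The log2 difference was 0.42 at 24 h (adjusted p = 0.255), which passed in a fit of those 2 groups alone (adjusted p = 0.00949), and 1.19 at 48 h (adjusted p = 7.84e-05). At 48 h 1984 genes differed, 934 higher and 1050 lower, and 155 at least 2-fold. Cd24 was 5.28-fold, Cyp1b1 3.42-fold and Ugt2b1 3.34-fold higher at 100 µM, while Gckr was 5.58-fold and Steap4 4.22-fold lower. Cd24 had a low signal of 175 ± 35.7 (SD, n = 5) at 1 µM. NRF2 targets were higher at 100 µM in 13 of 19 (17 adjusted over the list alone) at 24 h and in 15 of 19 (17) at 48 h, and glucose metabolism genes lower in 8 of 12 (10) and 8 of 12 (10); both lists kept their call with an estimated correlation at both times. Camera called 15 of 26 lists at 24 h and 13 at 48 h, of which 8 and 8 kept their call with an estimated correlation. CAR and PXR targets at 24 h were called higher, with 4 of 11 higher (5 higher and 2 lower adjusted over the list alone), a mean of 0.24 and a median of -0.04 (adjusted p = 0.189 with an estimated correlation), and lost the call without BNF 100 µM 24 h replicate 3 (adjusted p = 0.0614) or BNF 1 µM 24 h replicate 4 (adjusted p = 0.0505). The groups did not overlap for 1078 genes (7.58%) at 24 h and 1553 (10.9%) at 48 h, against 0.794% by chance. Median centring gave 612 genes at 24 h, and at 48 h 76.2% of the genes called were higher with it, against 47.1% here.

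Genes that changed at 1 µM largely changed in the same direction at 100 µM, in comparisons that share the vehicle arrays. At 24 h both doses called 231 genes higher and 315 lower, where independent lists would share 29.03 and 35.43. At 48 h they shared 28 and 59, against 3.61 and 6.38. The log2 fold changes of the doses correlated across genes, which are not independent replicates, with r = 0.597 at 24 h and 0.501 at 48 h. Simulated unchanged groups, with simulated vehicle arrays shared by the doses, gave a mean r of 0.5 (0.471 to 0.522 over 100 rounds) and 0.498 (0.468 to 0.53). The simulated genes were drawn independently of each other, so variation shared between genes is missing and the ranges may be too narrow. At 48 h the observed r lay within the simulated range, so this r alone shows no agreement beyond the shared vehicle. The covariances were 0.0936 and 0.0716, against simulated covariances of 0.0519 and 0.0516, which left differences of 0.0417 and 0.02. With the vehicle arrays split between the doses, which removed the shared controls and left 2 or 3 vehicle arrays per dose, r was 0.184 (0.143 to 0.206) at 24 h and 0.106 (0.0425 to 0.149) at 48 h. The doses then shared a median of 91.5 higher and 163 lower genes at 24 h, against 13.2 and 14.1 for independent lists. At 48 h the medians were 10 and 25.5, against 0.875 and 1.71.

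The 100 µM response held many genes in common between the times, whose vehicle arrays were separate. It shared 738 higher and 869 lower genes, against 133.9 and 127.3 for independent lists, with 13 genes called in opposite directions. At 1 µM the times shared 14 higher and 38 lower genes, against 0.782 and 1.78, with 1 opposite, and the sum of shared genes, 52, was 32 without vehicle 48 h replicate 1 and 34 without vehicle 48 h replicate 5. The log2 fold changes at the 2 times correlated across genes with r = 0.409 at 100 µM and 0.092 at 1 µM.

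**Figure D3:**
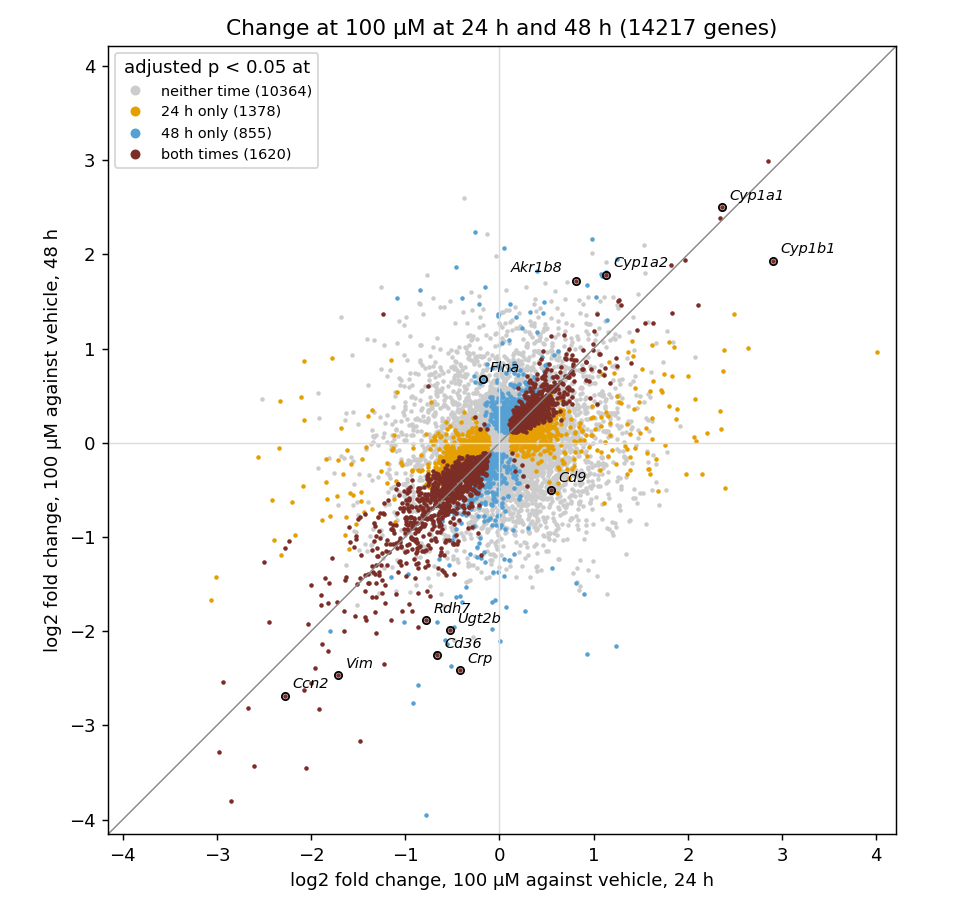
Log2 fold change of each of the 14217 genes at 100 µM against vehicle at 24 h (horizontal axis) and 48 h (vertical axis), coloured by the time at which it passed an adjusted p of 0.05, with a line of equal change. Of these genes 3000 were called at 24 h, 1620 of them also at 48 h, and 855 were called at 48 h alone. Crp, Cd36 and Ugt2b lie below the line.

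The effect of BNF itself differed between the times for 112 genes at 100 µM, 54 with a higher and 58 with a lower value at 48 h, by the test of the interaction. Crp had log2 fold changes of -0.42 at 24 h and -2.42 at 48 h (difference -1.99, SE 0.18). Cd36 had -0.67 and -2.25, Ugt2b -0.52 (adjusted p = 0.0737 in another probe set) and -1.99, and Rdh7 -0.78 and -1.88. Akr1b8, by contrast, had 0.81 at 24 h and 1.72 at 48 h (difference 0.91, SE 0.11). Cd9, a tetraspanin, had 0.55 and -0.50, and Aldh4a1, of proline breakdown, -0.72 and 0.02. Within the AhR battery, looked at after the values were seen, Cyp1b1 (difference -0.97, adjusted p = 0.0387) and Cyp1a2 (difference 0.66, adjusted p = 0.0423) passed the test, and each call was lost with median centring, without a mean-variance trend (Cyp1a2 also in a fit of the compared groups alone, adjusted p = 0.0876) and without any 1 of 14 of the 20 arrays, with adjusted p from 0.053 to 0.078 for Cyp1b1 and from 0.0521 to 0.0946 for Cyp1a2. Cyp1b1 kept its call without vehicle 24 h replicates 2 and 4, BNF 100 µM 24 h replicate 5, vehicle 48 h replicates 1 and 5 and BNF 100 µM 48 h replicate 1, and Cyp1a2 without vehicle 24 h replicates 3 and 4, BNF 100 µM 24 h replicates 2 and 3, vehicle 48 h replicate 5 and BNF 100 µM 48 h replicate 1. At 1 µM 13 genes passed, 7 higher and 6 lower, including Acly, which had log2 fold changes of -0.85 at 24 h and -0.35 at 48 h. This count lay between 2 and 22 when 1 array was left out, and it moved over 1.5 times with 15 of the 20 arrays, all but vehicle 24 h replicates 2 and 4, BNF 1 µM 24 h replicates 1 and 2 and BNF 1 µM 48 h replicate 1. It was 0 with median centring, where Acly had an adjusted p of 0.34, and at an unadjusted p below 0.05 limma gave 1319 genes here. Median centring gave 47 genes at 100 µM, 61.7% of them higher, against 48.2% here.

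Between 24 and 48 h in vehicle, sex-dependent P450s and CAR and PXR targets fell, and ER stress and heat shock genes rose. Sex-dependent P450s fell in 6 of 7 (6 adjusted over the list alone), with Cyp2c13 down 4.18-fold (log2 fold change -2.06, SE 0.13) and Cyp2c11, the main male-specific P450, 3.53-fold. CAR and PXR targets fell in 9 of 11 and rose in 1 (the same adjusted over the list alone), with Cyp3a2 down 4.20-fold, and Slc10a1 fell 4.68-fold. Cyp1a2 fell by 1.83 on the log2 scale and Tiparp fell by 0.48 (both named here after their values were seen). ER stress and amino acid response genes rose in 14 of 21 and fell in 1 (15 and 1 adjusted over the list alone), with Ddit3 up 1.52-fold, and heat shock genes rose in 6 of 10 (8 adjusted over the list alone), with Hspb1 up 1.51-fold. Bile acid synthesis and transport fell in 7 of 18 and rose in 1 (the same adjusted over the list alone), and liver-enriched transcription factors fell in 7 of 16 (7). Kupffer cell and macrophage markers fell in 6 of 15 (8 adjusted over the list alone; adjusted p = 0.0164 with an estimated correlation), among them Cd5l 2.45-fold (adjusted p = 0.269 in another probe set) and C1qb 1.73-fold. Stellate cell (1 of 17 lower, 1 adjusted over the list alone; adjusted p = 0.174) and endothelial markers (2 of 11 lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.322) were not called. Calls lost with an estimated correlation were hepatocyte secreted proteins (10 of 20 lower, 14 adjusted over the list alone; adjusted p = 0.0742 with an estimated correlation), glucose metabolism (7 of 12 lower, 7; adjusted p = 0.172), urea cycle and amino acid catabolism (11 of 21 lower and 1 higher, the same; adjusted p = 0.178) and oxidative phosphorylation (2 of 19 lower, 2; adjusted p = 0.581). The last was also lost without any 1 of vehicle 24 h replicates 2, 3 and 5 and vehicle 48 h replicates 3 and 4, with adjusted p from 0.0527 to 0.119, and with quantile normalization (adjusted p = 0.136), median centring (adjusted p = 0.113) and without genes below the median mean signal (adjusted p = 0.082). In all 2450 genes differed, 1228 higher and 1222 lower at 48 h, 192 of them at least 2-fold, and the groups did not overlap for 1654 genes (11.6%, against 0.794% by chance). Median centring gave 1633 genes.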

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

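The test of the spread between wells, all tests on the hepatocyte gene lists and all tests on Vim and Ccn2 were chosen after the results were seen, the marker tests among them were restricted to markers above the median signal after all markers had been looked at, and the requirement that a smaller 1 µM response exceed 2 SE was added after its ratio was seen to meet the criterion first set.

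BNF at 1 µM called fewer genes at 48 h (115) than at 24 h (612), while the effects differed between the times for 13 genes, a count of 2 to 22 when 1 array was left out. A larger spread of single genes between wells at 48 h is argued against, since the median gene SD of the vehicle and 1 µM arrays was 0.207 at 48 h and 0.212 at 24 h, a ratio of 0.977. The fit also shared 1 spread estimate per gene between the times. A spread shared by many genes stays open. Along the direction of largest variance across arrays (10.6%), vehicle arrays had an SD of 8.14 at 48 h and 2.77 at 24 h, and 1 µM arrays 5.26 and 6.58. Displacement of the 24 h vehicle arrays in a direction unrelated to BNF is argued against. Of the genes called at 1 µM and 24 h, 89.5% had the same sign at 100 µM and 48 h, against other vehicle arrays. Among all genes 60.5% had the same sign. Displacement along a direction in which BNF also moves the arrays would give the same signs and stays open. Along the direction of largest variance, mean scores at 24 h were -31.15 in vehicle and -15.78 at 1 µM. At 48 h they were 1.662 in vehicle and 33.06 at 100 µM. A smaller response at 48 h may account for the fewer calls. Over genes chosen with some vehicle arrays and measured with the others, the mean signed effect was 0.246 at 24 h and 0.137 at 48 h. The ratio was 0.558. The 1 µM effect was smaller at 48 h in each of the 100 choices of vehicle arrays, which overlap. At 100 µM, the dose at which these genes were chosen, the ratio was 1.02. A smaller response stays open, because the difference averaged 0.109 over the choices and the SE of 1 choice averaged 0.0694.

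At 100 µM and 48 h hepatocyte metabolic gene lists fell together, with a median log2 fold change of -0.28 over the 203 members of the 11 lists called lower, of which phase II conjugation (adjusted p = 0.439) and oxidative phosphorylation (adjusted p = 0.188) lost their call with an estimated correlation. A lower share of hepatocyte RNA, which raises the markers of the other cell types, is argued against by the 11 such markers above the median signal of all genes, whose median was -0.243 (SE 0.172) with 4 lower and 0 higher, while all 60 markers had a median of 0.0406 with 6 lower and 0 higher. Of the 11, 7 were Kupffer cell, 2 stellate cell, 1 endothelial, 1 cholangiocyte and 0 lymphocyte markers, so the test speaks mainly for Kupffer cells. Over all measured markers the medians were -0.18 for Kupffer cells and cholangiocytes, 0.238 for stellate cells, 0.187 for endothelial cells and 0.151 for lymphocytes. Scaling of the arrays was looked at with quantile normalization and with median centring, and 100% of the preset-correlation calls of the 11 lists stayed with both. Centring shifts all genes of an array by the same amount, while camera compares a list with the other genes. Centring could therefore hardly change these calls and says little about scaling. Quantile normalization can shift genes by their signal, and the calls did not depend on it. RNA degradation stays open: at 100 µM minus vehicle the 3' minus 5' log2 difference of Gapdh was -0.0174 (95% interval -0.0403 to 0.00562), below the bound of 0.1 set for it, but that of beta-actin was 0.0288 (95% interval -0.0853 to 0.143), which reaches past it. A regulated fall of these genes in hepatocytes also stays open and was not tested on its own.

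Vim and Ccn2, genes also expressed by stellate and fibroblast-like cells, were among the lowest at 100 µM and 48 h. Fewer such cells could account for this, and it cannot be told apart from a change in hepatocytes, because 2 stellate cell and fibroblast markers lay above the median signal of all genes: Lox at -1.30 (SE 0.23) and Sparc at -0.35 (adjusted p = 0.0578). Sparc was called lower among genes above the median of mean signal (adjusted p = 0.0309) and without vehicle 48 h replicate 1 (adjusted p = 0.0332), BNF 100 µM 48 h replicate 2 (adjusted p = 0.0379) or replicate 4 (adjusted p = 0.0328), while another Sparc probe set had 1.98 (adjusted p = 0.112). The median of all 17 markers was 0.238. A probe set that misreads its gene also stays open, since the array held 0 further probe sets with either gene as their 1 symbol. Probe sets with several symbols or none were not searched for these genes.

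In each comparison of 2 groups, 1 of 100 splits of the arrays, the real one, gave as many genes. For the differences of the effects between times, the additive effects of dose and time were removed first. The arrays were then dealt at random to the groups, and no deal gave as many genes as the unaltered data. With the real count included, this is the smallest share that 100 counts can give, and it was not adjusted over the 9 comparisons. It argues against chance among wells for all but the difference of the effects between times at 1 µM. At 24 h the real split gave 612 genes at 1 µM and the highest other 140, and 3000 against 755 at 100 µM. At 48 h the values were 115 against 3 at 1 µM and 2475 against 1035 at 100 µM. Between doses they were 1097 against 219 at 24 h and 1984 against 412 at 48 h, and in vehicle between times 2450 against 1336. For the difference of the effects between times the real count and that of the highest random deal were 112 against 8 at 100 µM. At 1 µM they were 13 against 12, and with a margin of 1 gene and a count of 0 with median centring, chance is left open. In the comparisons of 2 groups the highest other split exchanged 1 array between them.

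The effect of BNF differed between 24 and 48 h, by the test of that difference, for 13 genes at 1 µM and 112 at 100 µM. At 1 µM the differences were 0.519 for Slc6a9, 0.4969 for Acly, 0.387 for Itih1, 0.3611 for Copg1, 0.33 for Slc41a2, -0.603 for Sprr1a, -0.5452 for Pdrg1, -0.4932 for Fgfr1op2, -0.4614 for Sltm and -0.2735 for Arfrp1. In another probe set, where none was called, the direction reversed for Slc6a9 (-0.1667), Copg1 (-0.2291), Slc41a2 (-0.07412), Sltm (0.00276) and Arfrp1 (0.3296). With median centring all 10 of these calls were lost, with adjusted p from 0.22 for Slc6a9 to 0.634 for Slc41a2. Those of the 8 genes other than Slc6a9 and Acly were also lost without a mean-variance trend and when 1 array was left out, with adjusted p from 0.0514 to 0.104 in the latter. Of these 8, all but Copg1 were lost in a fit of the compared groups alone, with adjusted p from 0.0702 for Itih1 to 0.113 for Arfrp1, and Slc41a2, Sprr1a and Sltm with the block for rounds of serial numbers (adjusted p = 0.0561 each). All 8 were lost without any 1 of vehicle 24 h replicates 1 and 5, BNF 1 µM 24 h replicates 3 and 4, vehicle 48 h replicates 2 and 3 and BNF 1 µM 48 h replicates 2 and 5, and each without further arrays: in all 11 arrays for Itih1 and for Copg1, 12 for Fgfr1op2, 13 for Pdrg1, 14 for Sltm, 15 for Arfrp1, and 16 for Slc41a2 and for Sprr1a. At 100 µM they were 0.9087 for Akr1b8, 0.8586 for Cited2, 0.858 for Flna, 0.7636 for Fam149a, 0.7389 for Aldh4a1, 0.6563 for Cyp1a2, -0.9724 for Cyp1b1, -1.045 for Cd9, -1.103 for Rdh7, -1.462 for Ugt2b, -1.589 for Cd36 and -1.994 for Crp. The Flna call was lost, with adjusted p from 0.052 to 0.0726, without any 1 of vehicle 24 h replicates 1, 4 and 5, BNF 100 µM 24 h replicates 1 and 5, vehicle 48 h replicates 2, 3 and 4 and BNF 100 µM 48 h replicate 5. The Fam149a call was lost, with adjusted p from 0.05 to 0.068, without any 1 of vehicle 24 h replicate 1, BNF 100 µM 24 h replicates 1 and 4 and BNF 100 µM 48 h replicates 1 and 5, and in a fit of the compared groups alone (adjusted p = 0.0579).

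A single array stood apart from the other 4 of its group in 27 of 571 groups of values looked at, 4.73%, where chance gives about 5%. In vehicle at 24 h, with the range of the others in brackets, these were the signals of Angptl4 in replicate 1, 9073 (10110 to 10560), Soat1 in replicate 2, 230.3 (397.4 to 467.4), Lss in replicate 3, 1378 (1573 to 1660), Ddit3 in replicate 3, 11420 (9846 to 10230), Fabp1 in replicate 4, 2264 (2718 to 2929), Sdf2l1 in replicate 4, 2820 (3892 to 4343), and Ugt2b10 in replicate 4, 1361 (1722 to 1812). In vehicle at 48 h they were Fbp1 in replicate 2, 8926 (10670 to 11430), Proc in replicate 2, 4628 (5851 to 6407), Cox6a2 in replicate 5, 2976 (3536 to 3628), Cited2 in replicate 5, 11090 (6323 to 6960), Fam149a in replicate 5, 453.6 (566.5 to 611.2), and Ugt2b10 in replicate 5, 1820 (2414 to 2548).

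At 1 µM and 24 h, replicate 4 had a beta-actin 3' minus 5' difference of 1.462 (1.375 to 1.387 in the others) and a Cyp1b1 signal of 955.7 (535.8 to 631.4). At 1 µM and 48 h the signals were Slc6a9 in replicate 1, 8144 (6873 to 7117), Fbp1 in replicate 2, 9556 (7725 to 8149), and Sltm in replicate 3, 5752 (4556 to 4743). At 100 µM and 24 h they were Gdf15 in replicate 2, 3169 (4211 to 4556), Cyp3a23-3a1 in replicate 2, 78800 (60950 to 64410), and Hnf4a in replicate 4, 6646 (7423 to 7688). At 100 µM and 48 h they were, in replicate 1, Cyp1a1, 38670 (52140 to 55180), Cyp27a1, 11680 (12680 to 13060), Akr1c1, 42.39 (240.5 to 358.1), and Ugt2b10, 775.4 (1051 to 1174), with Cyp2a1 in replicate 2, 14360 (12900 to 13180), and Cd36 in replicate 4, 802.8 (615.1 to 653.1).

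Among the 10216 probe sets with several gene symbols or none, which the gene comparisons do not use, 133 differed from vehicle at 1 µM and 24 h, 58 higher and 75 lower. At 100 µM and 24 h 764 differed, 348 higher and 416 lower, at 1 µM and 48 h 9, 3 higher and 6 lower, and at 100 µM and 48 h 548, 212 higher and 336 lower. The shares called were 1.3%, 7.48%, 0.0881% and 5.36%, against 2.81%, 16.9%, 0.331% and 13% of the probe sets with 1 gene.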

How the results depend on the processing

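Median centring of the list tests and leaving out arrays for the correlation of doses and for the overlap of times were chosen after seeing the data. With centring on the array median the counts were 395 (51 higher, 344 lower) at 1 µM and 24 h, 66 at 1 µM and 48 h, 612 between doses at 24 h, 1633 in vehicle between times, 0 for the difference of effects at 1 µM (0 at least 2-fold) and 47 at 100 µM (7 at least 2-fold), while the other 3 counts stayed within 1.5 times. Among genes above the median of mean signal, where fewer are tested, 2-fold counts were 5 and 99 at 24 h, 4 and 130 at 48 h, 25 and 75 between doses, 57 in vehicle between times, and 0 and 6 for the differences of effects, whose count at 100 µM was 174, and the correlation of the doses across genes was 0.7853 at 24 h and 0.5672 at 48 h. With all non-control probe sets, more of which are tested, 2-fold counts were 51 and 521 at 24 h, 425 at 100 µM and 48 h, 118 and 258 between doses, 318 in vehicle between times and 19 for the difference of effects at 100 µM. A fit of the compared groups alone gave 30 genes (4 at least 2-fold) at 1 µM and 48 h and 5 for the difference of effects at 1 µM. That difference was 20 with quantile normalization, 4 without a mean-variance trend and 25 with array weights, and 0 at least 2-fold with a block for rounds of serial numbers, whose meaning is not given in the sources used here. Vehicle arrays split between the doses gave correlations of 0.1839 and 0.106; this removes the shared controls and also leaves 2 or 3 vehicle arrays per dose, and the parts of these changes were not separated. With an estimated correlation camera called 5 lists in place of 12 at 1 µM and 24 h, 9 in place of 14 at 100 µM and 24 h, 2 in place of 12 at 1 µM and 48 h, 8 in place of 15 and 8 in place of 13 between doses, and 7 in place of 11 in vehicle between times. At 100 µM and 48 h it called 11 in place of 13.

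Leaving out 1 array gave 406 to 689 genes (17 to 37 at least 2-fold) at 1 µM and 24 h, 46 to 153 (5 to 16) at 1 µM and 48 h, 2 to 22 (0 to 2) for the difference of effects at 1 µM, correlations of the doses of 0.554 to 0.634 and 0.4575 to 0.5604, and 32 to 75 genes shared between times at 1 µM. The count at 1 µM and 24 h moved over 1.5 times without BNF replicate 3 (406). Of 66 values from another probe set of a named gene, 30 kept direction and call, 23 lost the call, 1 gained it and 12 reversed, none of the reversed being called there: Hnf4a 0.1343 (1 µM, 24 h), 0.01551 (100 µM, 24 h) and 0.1216 (vehicle), Mx2 0.3477, Cdh1 0.6448, Map2 -0.6107, Sesn2 -0.2332, Slc6a9 -0.1667, Copg1 -0.2291, Slc41a2 -0.07412, Sltm 0.00276 and Arfrp1 0.3296. The stellate cell list at 1 µM and 48 h reversed among genes above the median of mean signal, with a median of -0.5419 over the 2 markers left (adjusted p = 0.0119). Where no construction is named, the cause was not tested. Of 303 results of named genes, 22 lost their call with median centring, 21 in a fit of the compared groups alone, 15 without a mean-variance trend, 4 with the block, 1 with array weights, and 0 with log2 of the signal plus 16 or with quantile normalization. Leaving out 1 array changed the call of 29 of these results, in 217 of 3250 values by losing it and in 5 by gaining it. Of 182 list tests, 40 lost their call with an estimated correlation, 3 with quantile normalization (4 gained it), 2 with median centring (2 gained it) and 1 with the block, while 9 of 161 lost it among genes above the median of mean signal (3 gained it and 1 reversed), and leaving out 1 array ended the call in 23 of 1820 values and gave one in 17. Signal over background limits genes of low signal: the 10 measured lymphocyte markers had a median mean log2 signal of 6.44, against 9.32 for Kupffer cell markers.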

Other observations

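All families below were counted after the data were seen. Of 17 gene families counted, those described here were chosen from their values. Over all 14217 genes 21.1% were called at 100 µM and 24 h (1523 higher, 1477 lower) and 17.4% at 48 h (1250 higher, 1225 lower). The family counts were not tested against these shares, and a count near them says nothing particular about a family. Among 57 measured P450 genes 8 rose and 18 fell at 100 µM and 24 h, and 8 rose and 17 fell at 48 h. Cyp2e1, which metabolises ethanol, had a log2 fold change of -1.16 at 100 µM and 48 h, Cyp2d2 -1.26 and Cyp2d3 -1.37, while Cyp2f4 had 0.56. Among conjugating enzymes, sulfotransferases fell in 5 of 14 at 100 µM and 24 h and in 3 at 48 h, with 0 higher at either time. Other conjugating enzymes went both ways. Glutathione S-transferases rose in 1 and fell in 7 of 16 at 24 h, and rose in 2 and fell in 6 at 48 h, with Gsta4 at 0.84 and Gstm3 at -1.95 at 48 h. Glucuronosyltransferases rose in 1 and fell in 3 of 9 at 48 h, with Ugt2b1 at 1.19 and Ugt2b10 at -1.18.

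Of 32 amino acid transporters 6 rose and 1 fell at 100 µM and 24 h, and 6 rose and 2 fell at 48 h, with Slc1a4 at 0.89 and Slc7a5, a carrier of large neutral amino acids, at 0.62 at 48 h. Serpins, many of them secreted by the liver, rose in 2 and fell in 11 of 33 at 24 h, and rose in 2 and fell in 12 at 48 h. Apolipoproteins fell in 5 of 16 at 24 h and in 6 at 48 h, with 0 higher at either time. Of 55 ribosomal protein genes 4 rose at 24 h and 2 at 48 h, with 0 lower.

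Ccn2, a target of the transcriptional regulators YAP and TEAD, was among the lowest genes at 100 µM, so the hypothesis that BNF lowered other YAP and TEAD targets was tested. A list of 20 such genes, written after Ccn2 was seen and before its members were looked at, left Ccn2 out, and 19 were measured. The camera p was 0.212 at 24 h, with 5 lower, and 0.106 at 48 h, with 3 lower and 1 higher, so a fall of the list was not found.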
